A study of Mus musculus with 19 samples.

How the data were processed

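Macrophages and Ly6C+ inflammatory monocytes had been sorted from the bone marrow of healthy mice and of mice with bone metastases; no other sort marker is given in the sources used here. Per the labels, 100000 MetBo2 cells were injected into the heart of female mice at 4 weeks of age, RNA was extracted with a column kit and checked on a bioanalyzer, and labelled RNA was hybridised to Affymetrix MoGene 2.0 ST arrays. The labels name oligo, an R package for such arrays, as the processing tool; its version, the background correction, the normalization and the rule that turned probe sets into genes are not given in the sources used here. The deposited values are on a log2 scale, as judged from their range of 1.38 to 12.6, with 1 value per gene symbol and array for 20998 genes and 19 arrays and no missing values. Of the symbols, 20573 were current symbols in the RefSeq annotation of the mouse genome, 350 only synonyms and 75 neither, and all 20998 were tested. The array medians lay between 4.45 and 4.55, and the values were used as deposited, with scaling only among the alternatives below.

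The 19 arrays fell into 4 groups by cell type and marrow, and replicate numbers were assigned in the order of the labels. No pairing between macrophages and monocytes of the same mouse is stated, so none was modelled. As a check of the labels, 4 Y-linked genes lay between 2.12 and 2.87 on all arrays and Xist between 10.7 and 11.0, the pattern of female mice on every array.

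Group means were fitted to all 19 arrays at once with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no intensity filter), and 5 contrasts were taken: metastasis against healthy in each cell type, macrophages against monocytes in each kind of marrow, and the interaction, which is the metastasis effect in macrophages minus that in monocytes. P-values were adjusted by the Benjamini-Hochberg method over all 20998 genes, and a gene passed at an adjusted p below 0.05. Positive log2 fold changes mean higher in metastasis, or higher in macrophages. The method was tested on simulated data with 200 changed genes: with the layout of the macrophage comparison, 62% of genes changed by 0.5 on the log2 scale, 96% of those changed by 1 and 100% of those changed by 2 were found, and for the interaction 22%, 92% and 100%. Of the genes called in the simulated data, between 3.24% and 5.79% had not been changed. The simulated arrays had 1 spread per gene in all 4 groups, and genes that varied independently. In the data the median SD was 0.198 in healthy and 0.171 in metastasis macrophages, against 0.140 and 0.135 in monocytes. The percentages from the simulation therefore need not hold for these comparisons.

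There were 29 gene lists, of macrophage activation and function, metabolism, cell cycle, stress, and markers of other cell types that the sorts could hold. Each list was tested in each comparison by camera with a preset correlation of 0.01 between genes, by camera with an estimated correlation and by fry, which tests whether the genes of a list move on balance in one direction and does not set them against other genes. P-values of lists were adjusted over the 29 lists within a comparison, and those of 2 lists added later over all 31. Members of each list were also adjusted over the list alone. List members that carry no value under their symbol or a synonym were not used here, among them Ly6g, Hba-a1, Vpreb1 and Tubb1.

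Groups, contrasts, tests, gene lists and the rule for naming genes were fixed before the data were examined. The rule took, in each comparison of metastasis with healthy marrow, the 10 largest rises and the 10 largest falls among genes past the threshold whose groups did not overlap, and in each other comparison the 6 largest each way among genes past the threshold. From each list it took up to 4 members past the threshold with the smallest adjusted p and, where most members did not pass, up to 2 others with the highest mean level. Il4ra, Msr1, Ccr2, Flt1, Csf1r, Csf1, Adgre1, Ly6c2, Cx3cr1, Itgam and Ccl2 were always named, and predicted transcripts, small RNAs and antigen receptor segments were counted but not named. Not all genes that the rule takes are reported here, and in the comparisons of cell types only some of them. The metastasis effects of the cell types were compared by Pearson and Spearman correlation across genes and by the overlap of calls.

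The alternatives tried were a fit of the 2 groups compared alone, eBayes with an intensity trend and robust hyperparameters, array weights, a filter that kept 11005 genes whose highest group mean lay above the median gene mean of 4.51, quantile normalization of the deposited values, equal array medians, an added 2-fold threshold, and each array left out in turn. Chosen after the data were seen were fits without the array of each group that correlated least with its group, fits without 2 macrophage arrays that lay between their groups, and 2 further gene lists, of plasma cells and of interferon gamma response. Alternatives on several probe sets per gene could not be run, because the table holds 1 value per gene. To ask whether chance could give a result as large, the arrays were regrouped in 100 splits per comparison, the real one included. Principal components were computed on the values of all genes, centred by gene.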

Results

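Gene expression was measured in macrophages and Ly6C+ inflammatory monocytes sorted from mouse bone marrow, on 19 Affymetrix gene arrays. The marrow came either from healthy mice or from mice with bone metastases of MetBo2, a bone-homing clone of the Met-1 mammary tumour cell line, which had been injected into the heart. The 4 groups were macrophages from healthy marrow (n = 5 arrays), macrophages from metastasis (n = 5), monocytes from healthy marrow (n = 5) and monocytes from metastasis (n = 4). Each array held log2 expression values for 20998 genes, and the array medians lay between 4.45 and 4.55. The number of arrays per group limited the precision of every comparison, with a median standard error of 0.11 on the log2 scale for the difference between healthy and metastasis macrophages. The labels did not say that the arrays of a group came from separate mice, so the p-values measure the spread between these samples only. Neither an age nor an injection is given for the healthy mice, and no batch is given for any array. Differences in age, injection or batch therefore cannot be told apart from an effect of the tumour.

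The sorted cell type separated the arrays more than the tumour did. The first principal component held 58.3% of the variance and parted macrophages from monocytes, and the second held 7.0%. Arrays of macrophages and monocytes correlated with each other at r = 0.961 to 0.970 across genes, and the highest correlation between any 2 arrays was 0.994. Macrophages healthy replicate 1 lay apart from its group on the second component.

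**Figure D1:**
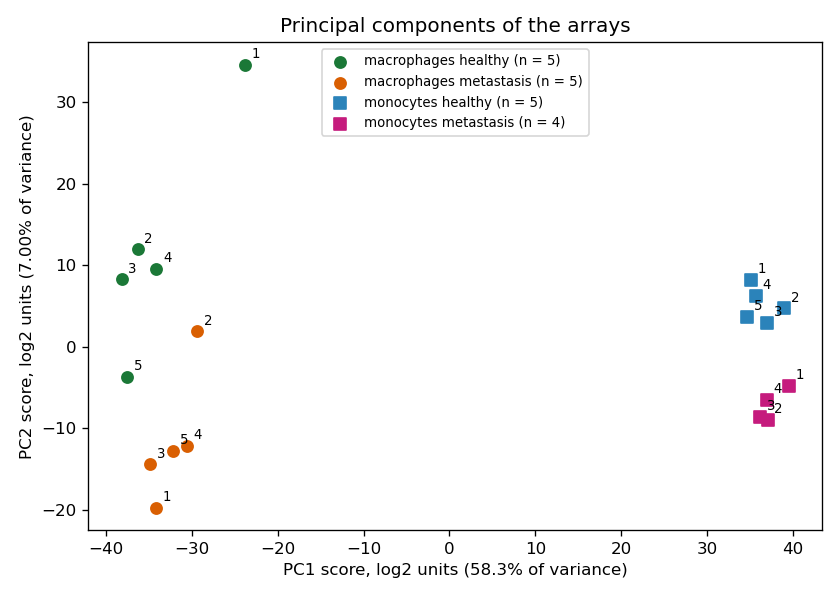
Scores of the 19 arrays on the first and second principal components (log2 units), with circles for macrophages, squares for monocytes and the replicate number beside each point. Macrophages lie on the left of the first component, which holds 58.3% of the variance, and monocytes on the right; macrophages healthy replicate 5 and metastasis replicate 2 lie nearest to the other group on the second component, which holds 7.0%.

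The first question was how the sorted marrow macrophages differ when breast cancer has spread to bone. These arrays also carried genes of other blood cells, as described below. A difference may therefore lie in the macrophages or in the mix of sorted cells, which these values do not separate. In macrophages from metastasis, Saa3, an acute-phase serum amyloid gene, rose 14.4-fold (log2 3.85 ± 0.41, SE), from 3.81 ± 0.19 (SD, n = 5) to 7.66 ± 1.09 (SD, n = 5). Lipg, which encodes endothelial lipase, rose 12.3-fold (3.62 ± 0.29, SE). The chemokine genes Cxcl9, Cxcl11 and Cxcl10, which interferon gamma is known to induce, rose 5.74-fold, 5.05-fold and 2.67-fold, and the complement gene Cfb rose 4.26-fold. Of genes that act in fatty acid uptake and handling, Fabp4 fell by 2.30 ± 0.32, Cd36 fell by 1.96 ± 0.25 and Lpl fell by 1.48 ± 0.19 on the log2 scale (SE). The mannose receptor gene Mrc1 fell by 1.34 ± 0.20, and of the plasma cell genes Jchain fell by 2.08 ± 0.28 and Tnfrsf17 fell by 1.69 ± 0.17.

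By limma, 259 of 20998 genes passed the adjusted threshold in macrophages, 134 higher and 125 lower in metastasis, and 54 of them differed by at least 2-fold. The balance turned to 144 higher and 154 lower after quantile normalization and to 96 and 145 with equal array medians. Of all genes, 405 (1.93%) had no overlap between the arrays of the groups, a state that chance gives 0.794% of genes with 5 and 5 arrays, and 149 of these were among the 259. Besides the genes above, the largest rises without overlap were in Stfa2l1 (2.23 ± 0.46, SE), a stefin A family gene, the immunity-related GTPase gene Iigp1 (1.73 ± 0.32), the chemokine gene Xcl1 (1.62 ± 0.25) and Npl (1.60 ± 0.17). The call of Stfa2l1 was lost with array weights (adjusted p = 0.0588). The largest falls without overlap were in Slc12a2, an ion cotransporter gene (-1.93 ± 0.26), the prostaglandin-degrading enzyme gene Hpgd (-1.49 ± 0.22), the C-type lectin gene Clec4b1 (-1.28 ± 0.18), Dennd5b (-1.21 ± 0.18) and Hid1 (-1.19 ± 0.19). The count rose to 546 without macrophages healthy replicate 5 and fell to 165, 153 and 162 without metastasis replicate 1, 4 or 5. It was 134 with array weights, 65 in a fit of the 10 macrophage arrays alone, and 726 when healthy replicate 5 and metastasis replicate 2, which lay between the groups, were both left out. Macrophage arrays varied more within their groups (median SD 0.198 and 0.171) than monocyte arrays (0.140 and 0.135). The main fit shares 1 spread per gene among all groups, which favours calls in the noisier cell type. The counts of 259 here and 108 in monocytes therefore do not show which cell type differed more. The fit of the macrophage arrays alone ended the calls of 23 named genes described below, from Prtn3 (adjusted p = 0.0695) to Mki67 (0.219), and array weights ended 16, up to Socs3 (0.129).

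Interferon-response genes were higher as a group in metastasis macrophages. Of 27 genes, 4 rose and 23 did not pass (11 rose when adjusted over the list alone), with a median log2 fold change of 0.35. Camera placed the list higher (adjusted p = 2.7e-08, but adjusted p = 0.341 with an estimated correlation). The genes that rose were Cxcl10 (1.42 ± 0.23, SE), Ifi44 (0.80 ± 0.14), Oas2 (1.28 ± 0.32) and Oasl2 (0.95 ± 0.24). Oas2 and Oasl2 lost their calls in 8 and 9 of the 10 fits that each left out 1 macrophage array (adjusted p up to 0.116). Among 23 genes of pro-inflammatory activation 2 rose, Cxcl9 (2.52 ± 0.34) and Socs3 (0.55 ± 0.14), 2 also when adjusted over the list alone. Camera found no shift of the list (adjusted p = 0.124) except without healthy replicate 1 (0.0149). Socs3 lost its call in 8 of those 10 fits (adjusted p up to 0.117).

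Cell cycle genes were also higher in metastasis macrophages. Of 28 genes, 27 had positive fold changes with a median of 0.36. Over all genes 3 passed the threshold, and 20 when adjusted over the list alone (camera adjusted p = 2.9e-16, but adjusted p = 0.341 with an estimated correlation). The genes that passed were Mki67 (0.41 ± 0.09, SE), a proliferation marker, Kif11 (0.59 ± 0.14) and Ube2c (0.54 ± 0.13). Each lost its call in 5 to 8 of the 10 fits with 1 macrophage array left out (adjusted p up to 0.110, without metastasis replicate 1). Pcna stood at 0.15 ± 0.09. The glucose transporter gene Slc2a1 rose by 0.59 ± 0.09, the only gene past the threshold among 21 of glycolysis and hypoxia (3 adjusted over the list alone), whose median was 0.14. None of 29 oxidative phosphorylation genes passed in limma over all genes or when adjusted over the list alone, although 28 had positive fold changes with a median of 0.13. Among 18 cholesterol synthesis genes Idi1 rose (0.74 ± 0.14) at a list median of 0.13 (2 adjusted over the list alone). Camera placed these metabolic lists higher (adjusted p = 0.00682, 2.2e-05 and 0.00682), but not with an estimated correlation (adjusted p = 0.341, 0.341 and 0.411).

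Some lipid-associated macrophage genes fell. Of 18 genes, 4 fell and 14 did not pass (2 rose and 5 fell when adjusted over the list alone): Fabp4, Cd36, Lpl and the lipid-sensing receptor gene Pparg (-1.01 ± 0.22, SE). The median of the list was only -0.03 while its mean was -0.36, since a few genes fell steeply (camera adjusted p = 0.0141 downward, but adjusted p = 0.341 with an estimated correlation). Pparg lost its call in 6 of the 10 fits with 1 array left out (adjusted p up to 0.0574).

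Markers of marrow-resident macrophages were lower as well. Of 20 genes, Hpgd, Mrc1 and the red pulp and marrow macrophage factor Spic (-0.67 ± 0.15, SE) fell and 17 did not pass (3 rose and 7 fell when adjusted over the list alone). The median was -0.19 (camera adjusted p = 0.00935, but adjusted p = 0.411 with an estimated correlation). The camera call ended without macrophages healthy replicate 1 (adjusted p = 0.0625) or metastasis replicate 2 (adjusted p = 0.0807), and Spic lost its own call in 5 of the 10 fits (adjusted p up to 0.0828). Among 21 genes of alternative activation and the IL-4 response 3 fell and 1 rose (5 and 3 when adjusted over the list alone). The median was -0.18 (camera adjusted p = 0.0308, but adjusted p = 0.411 with an estimated correlation). Mrc1, the lectin gene Clec10a (-1.05 ± 0.22) and the transcription factor gene Irf4 (-1.09 ± 0.23) fell, while Il4ra, which encodes the interleukin-4 receptor alpha chain, rose (0.49 ± 0.10). The camera call of this list ended without healthy replicate 1 (adjusted p = 0.165), healthy replicate 4 (0.0567), metastasis replicate 1 (0.05001) or metastasis replicate 4 (0.114), and with dim genes left out (0.0820). Clec10a and Irf4 lost their calls in 3 and 4 of the 10 fits (adjusted p up to 0.0587 and 0.0629). Il4ra lost its call without healthy replicate 4, metastasis replicate 4 or metastasis replicate 5 (adjusted p = 0.0519, 0.0656 and 0.0635), with array weights (0.0585) and in a fit of the 10 macrophage arrays alone (0.133).

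Among 26 genes of matrix remodelling and angiogenesis, Mmp14 (1.15 ± 0.27, SE), Mmp19 (0.55 ± 0.13) and Tgfbi (0.50 ± 0.11) rose, 3 also when adjusted over the list alone. Camera found no shift (adjusted p = 0.672), with a list median of -0.01 and a mean of 0.06. Each of these 3 genes lost its call in 6 or 7 of the 10 fits with 1 array left out (adjusted p up to 0.106, without metastasis replicate 1). Of 17 chemokine and receptor genes, Ccl12 rose to 3.85 ± 0.74 (SD) from a healthy level no higher than that of Y-linked genes, which female mice lack, so its difference has no exact value. In the same list Cx3cr1, the fractalkine receptor gene, fell (-0.64 ± 0.16, SE), with 2 up and 2 down when adjusted over the list alone (median -0.06, mean 0.04, camera adjusted p = 0.780). The call of Ccl12 ended in a fit of the macrophage arrays alone (adjusted p = 0.0958), and that of Cx3cr1 in 8 of the 10 fits with 1 array left out (adjusted p up to 0.117, without healthy replicate 1). The osteoclast list had 1 gene of 14 past the threshold, the integrin gene Itgb3 (-0.56 ± 0.13; camera adjusted p = 0.274), which lost its call in 8 of the 10 fits (adjusted p up to 0.106). No gene passed in limma over all genes among 25 lysosomal, 10 MHC class II, 11 MHC class I presentation and 16 immune suppression and checkpoint genes (1 lysosomal gene fell when adjusted over the list alone). Camera gave adjusted p = 0.817, 0.274, 0.777 and 0.349 for these lists, and 2856 of all genes had an unadjusted p under 0.05. Further receptor and ligand genes chosen beforehand did not pass in macrophages: Msr1 stood at 0.35 ± 0.13, Ccr2 at 0.12 ± 0.12, Flt1 at -0.19 ± 0.18, and Csf1r at -0.35 ± 0.16. Csf1 stood at 0.15 ± 0.13, Adgre1 at -0.35 ± 0.15, Ly6c2 at 0.23 ± 0.11, Itgam at -0.05 ± 0.10 and Ccl2 at -0.10 ± 0.22.

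Markers of other blood cells moved alongside these groups in the macrophage arrays. B lineage genes were lower in metastasis, with Jchain, Rag1 (-0.86 ± 0.17, SE) and Ebf1 (-0.60 ± 0.14) falling among 17 genes (1 rose and 5 fell when adjusted over the list alone). The median was -0.24, and Cd79a stood at -0.89 ± 0.37 (camera adjusted p = 4.8e-06, but adjusted p = 0.341 with an estimated correlation). Ebf1 lost its call in 7 of the 10 fits with 1 array left out (adjusted p up to 0.101), and Rag1 in a fit of the macrophage arrays alone (0.0695). T and NK cell genes were higher, with a median of 0.43 over 17 genes and Cd8a past the threshold (0.69 ± 0.13; 2 adjusted over the list alone). Nkg7 stood at 0.48 ± 0.14 and Cd3d at -0.39 ± 0.19 (camera adjusted p = 0.00107, but adjusted p = 0.341 with an estimated correlation and 0.0765 with dim genes left out). Neutrophil precursor genes were higher too, with a median of 0.16 over 11 genes and Prtn3, a granule protease gene, past the threshold (0.96 ± 0.17; 2 adjusted over the list alone). Camera gave the list an adjusted p = 0.00935, but adjusted p = 0.449 with an estimated correlation. That call ended without healthy replicate 1 (adjusted p = 0.213) or metastasis replicate 1 (0.05001). Prtn3 and Cd8a did not pass in a fit of the macrophage arrays alone (adjusted p = 0.0695 and 0.0709). The maturing neutrophil list had a median of 0.08 over 16 genes and none past the threshold in limma (2 adjusted over the list alone; camera adjusted p = 0.0429, but adjusted p = 0.512 with an estimated correlation). Its camera call was lost after quantile normalization (adjusted p = 0.0846) and in 6 of the 10 fits (adjusted p up to 0.236, without healthy replicate 1).

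Other markers showed no shift of their lists by camera in macrophages. Vcan rose (1.47 ± 0.26, SE) among 16 Ly6C-high monocyte genes (adjusted p = 0.274, but 0.0109 without healthy replicate 1). Clec4b1 and Cd209a (-1.02 ± 0.24) fell among 15 dendritic cell genes, which had a median of 0.01 and a mean of -0.10 (adjusted p = 0.274, but 0.0385 without metastasis replicate 2). Cd209a lost its call in 6 of the 10 fits (adjusted p up to 0.108). Car1 fell (-0.74 ± 0.16) among 15 erythroid genes (adjusted p = 0.274), a call lost without healthy replicate 2 or metastasis replicate 1 or 4 (adjusted p up to 0.0630). Ier3 rose (0.62 ± 0.13) among 18 immediate early and stress genes (median 0.02, mean -0.03, adjusted p = 0.914), a call lost without metastasis replicate 4 (adjusted p = 0.0534). None of 22 epithelial tumour cell genes passed in limma over all genes (2 rose when adjusted over the list alone), and their mean fold change was 0.02 (adjusted p = 0.994). Nor did any of 15 eosinophil and basophil, 21 stromal and bone-forming and 14 endothelial genes pass over all genes (adjusted p = 0.349, 0.994 and 0.274). Itgb3 was the only one of 13 megakaryocyte and platelet genes that did (adjusted p = 0.196).

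**Figure D2:**
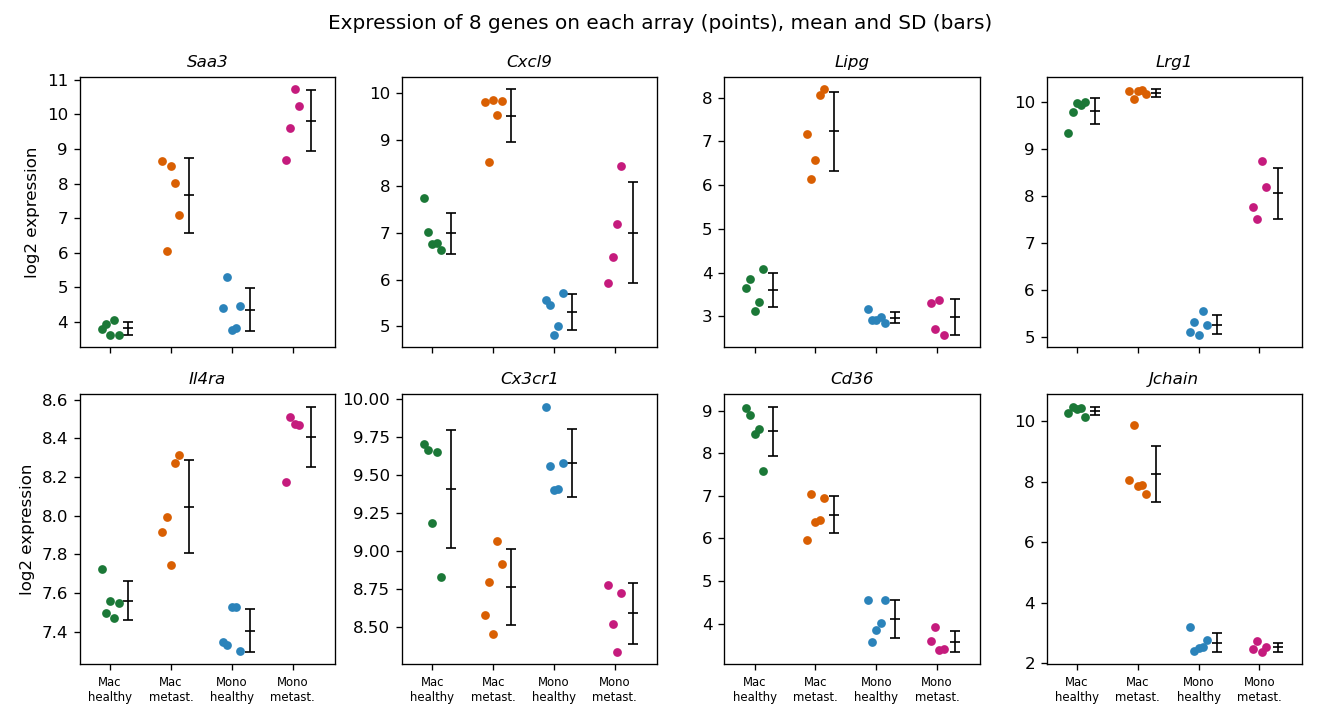
Log2 expression of 8 genes on each array (points) by cell type and marrow, with the group mean and SD as bars (n = 5 arrays per group, 4 for monocytes from metastasis). Saa3, Cxcl9 and Il4ra are higher in metastasis in both cell types and Cx3cr1 is lower; Lipg rises and Cd36 and Jchain fall in macrophages, and Lrg1 rises in monocytes, where Lipg stands at 0.02 ± 0.31 and Jchain at -0.15 ± 0.29 (log2, SE).

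The second comparison asked the same of Ly6C+ monocytes. Saa3 showed the largest rise here too, 43.9-fold (log2 5.46 ± 0.43, SE), from 4.36 ± 0.62 (SD, n = 5) to 9.81 ± 0.88 (SD, n = 4). Lrg1, which encodes a secreted leucine-rich glycoprotein, rose 6.99-fold (2.81 ± 0.18), the junctional adhesion molecule gene F11r rose 4.79-fold (2.26 ± 0.27), Wfdc21 rose 4.22-fold (2.08 ± 0.28) and the interleukin-1 family gene Il1f9 rose 3.59-fold (1.85 ± 0.21). Il4ra rose by 1.00 ± 0.11, from 7.41 ± 0.11 to 8.41 ± 0.16 (SD), with an adjusted p of 2.7e-05 in limma. The lectin gene Cd209a fell by 2.17 ± 0.26, Il12rb2, a chain of the interleukin-12 receptor, fell by 1.27 ± 0.21, and Cx3cr1 fell by 0.99 ± 0.17.

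In monocytes 108 of 20998 genes passed in limma, 83 higher and 25 lower in metastasis, and 42 differed by at least 2-fold. Of all genes, 1135 (5.41%) had no overlap between the groups, a state that chance gives 1.59% of genes with 5 and 4 arrays, and 107 of these were among the 108. Further rises without overlap were in Dpep2 (1.81 ± 0.32, SE), the triglyceride synthesis gene Dgat2 (1.80 ± 0.25), Cxcl9 (1.69 ± 0.37), Il18rap (1.65 ± 0.23), a chain of the interleukin-18 receptor, and the fatty acid binding protein gene Fabp7 (1.63 ± 0.26). Further falls were in Itgb3 (-1.08 ± 0.14), Mtss1 (-1.04 ± 0.15), Cgnl1 (-1.03 ± 0.23), Padi2 (-0.99 ± 0.19), Olfr433 (-0.96 ± 0.18), Il15 (-0.82 ± 0.17) and the lipoxygenase gene Alox5 (-0.79 ± 0.16). Cxcl9, Cgnl1, Padi2, Olfr433, Il15 and Alox5 lost their calls in 6, 7, 2, 1, 4 and 5 of the 9 fits with 1 monocyte array left out. The adjusted p rose to 0.136 for Cxcl9 without metastasis replicate 3 and to 0.198 for Cgnl1 without metastasis replicate 2. The count fell to 64 and 61 without monocytes metastasis replicate 2 or 3, and was 328 with array weights and 210 in a fit of the 9 monocyte arrays alone.

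Within the lists, few monocyte genes passed the threshold over all genes. Il4ra was the only one of 21 genes of alternative activation that passed (2 up and 2 down when adjusted over the list alone; camera adjusted p = 0.761). Cxcl9 and Socs3 (0.66 ± 0.14, SE) rose among 23 pro-inflammatory genes (2 up and 1 down over the list alone; camera adjusted p = 0.173). Ier3, a stress-induced gene, rose by 1.35 ± 0.14 among 18 immediate early and stress genes (5 up and 1 down over the list alone). Apoc1 rose (1.02 ± 0.19) among 18 lipid-associated genes, Mmp19 (0.70 ± 0.14) among 26 of matrix remodelling, and Acp5, the gene of tartrate-resistant acid phosphatase, among 14 osteoclast genes (0.51 ± 0.11). Vcan rose (1.33 ± 0.27) among 16 Ly6C-high monocyte genes and Lcn2 (1.14 ± 0.22) among 16 maturing neutrophil genes. Camera found no shift of these 5 lists (adjusted p = 0.634, 0.722, 0.784, 0.173 and 0.385). The matrix list had a median of -0.05 and a mean of 0.07, and the osteoclast list, in which Itgb3 fell, a median of 0.02 and a mean of -0.05. Adjusted over each of the 5 lists alone, 3, 5, 1, 2 and 6 genes rose and 2, 1, 1, 0 and 5 fell. Cx3cr1 was the only gene past the threshold among 17 of chemokines and receptors (camera adjusted p = 0.634), Cd209a among 15 dendritic cell genes (0.348) and Itgb3 among 13 megakaryocyte and platelet genes (0.0612). The last list was lower by camera without monocytes healthy replicate 2 or 3 or metastasis replicate 2 or 3 (0.0200, 0.00746, 0.0183 and 0.0327), and with equal array medians (0.0441). Slc2a1 rose by 0.47 ± 0.10. Socs3, Slc2a1, Mmp19, Acp5 and Vcan lost their calls in 6, 7, 2, 6 and 4 of the 9 fits with 1 array left out (adjusted p up to 0.198, for Socs3 without metastasis replicate 2). Apoc1 and Lcn2 lost theirs in a fit of the monocyte arrays alone (adjusted p = 0.0518 and 0.0906).

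Camera placed 4 lists higher in metastasis monocytes: oxidative phosphorylation (median 0.10, adjusted p = 0.0042), cholesterol synthesis (median 0.16, adjusted p = 0.0135), glycolysis and hypoxia (median 0.11, adjusted p = 0.0342) and immediate early and stress genes (median 0.09, adjusted p = 0.0342). With an estimated correlation the adjusted p was 0.739, 0.739, 0.739 and 0.668, and after quantile normalization 0.0715, 0.0715, 0.148 and 0.148. The call of the cholesterol list also ended without healthy replicate 1 or 4 or metastasis replicate 4 (adjusted p up to 0.668). That of the glycolysis list ended without healthy replicate 1 or 5 or metastasis replicate 1 or 4 (up to 0.113), and that of the immediate early list without healthy replicate 5 or metastasis replicate 3 (up to 0.0907). No gene passed in limma over all genes, or when adjusted over the list alone, among 27 interferon-response genes (median 0.12, camera adjusted p = 0.173) and 28 cell cycle genes (median 0.08, 0.173). The same held for 17 B lineage genes (median -0.07, 0.638), 17 T and NK cell genes (median -0.04, 0.650) and 22 epithelial tumour cell genes (median 0.01, mean -0.03, 0.741), in a comparison where 1592 of all genes had an unadjusted p under 0.05. Without monocytes metastasis replicate 3 the interferon list was higher by camera (adjusted p = 2.9e-07) and the cell cycle list too (0.0113). Of the receptor and ligand genes chosen beforehand, Msr1 stood at 0.15 ± 0.14 (SE), Ccr2 at 0.11 ± 0.13, Flt1 at -0.20 ± 0.20, and Csf1r at -0.12 ± 0.17. Csf1 stood at -0.03 ± 0.13, Adgre1 at -0.01 ± 0.16, Ly6c2 at 0.11 ± 0.12, Itgam at 0.13 ± 0.10 and Ccl2 at 0.45 ± 0.23, and none of these genes passed.

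**Figure D3:**
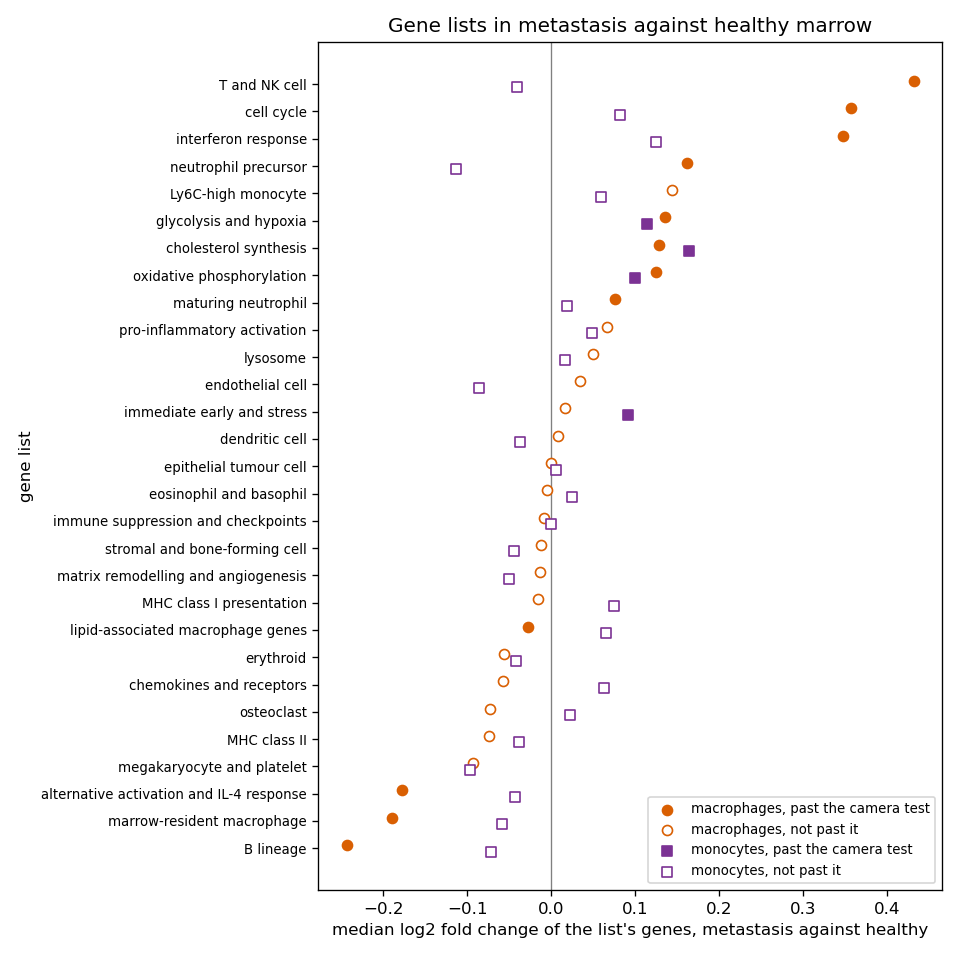
Median log2 fold change of each of 29 gene lists, metastasis against healthy marrow, in macrophages (circles) and monocytes (squares), with filled symbols for lists past camera's threshold. In macrophages the T and NK cell, cell cycle and interferon lists lie highest (0.43, 0.36 and 0.35) and the B lineage list lowest (-0.24); in monocytes 4 lists are filled, with medians from 0.09 to 0.16, and no list in either cell type passes with an estimated correlation.

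The metastasis differences of the macrophage and monocyte arrays overlapped in part. Across 20998 genes the 2 log2 fold changes correlated with Pearson r = 0.264 and Spearman rho = 0.162, and genes are not independent replicates. Saa3, Cxcl9, Cfb, Npl, Vcan, Il4ra, Socs3, Slc2a1, Mmp19, Ier3, Il1f9 and F11r were among 20 genes that rose in both cell types, and Cd209a, Cx3cr1, Itgb3 and Mtss1 among 5 that fell in both. Independent calls would share 0.530 rising and 0.149 falling genes, the comparisons share no arrays, and no gene passed in opposite directions. The calls need not be independent, however, since both tests used the same spread per gene. Whether macrophages and monocytes came from the same mice is not stated. The macrophage arrays also carried Ly6C-high monocyte genes, with a list mean of 8.97 in healthy macrophages against 9.94 in healthy monocytes. Part of the overlap may therefore lie in the mix of cells in the macrophage sort, which was not tested. Of the 259 genes past the threshold in macrophages, 216 (83.4%) had the same sign in monocytes, and of the 108 past it in monocytes, 97 (89.8%) had the same sign in macrophages. The share with the same sign over all genes was not computed. Cfb rose by 1.15 ± 0.24 (SE) and Npl by 0.89 ± 0.18 in monocytes, and lost those calls in 6 and 4 of the 9 fits with 1 monocyte array left out (adjusted p up to 0.112 and 0.133).

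**Figure D4:**
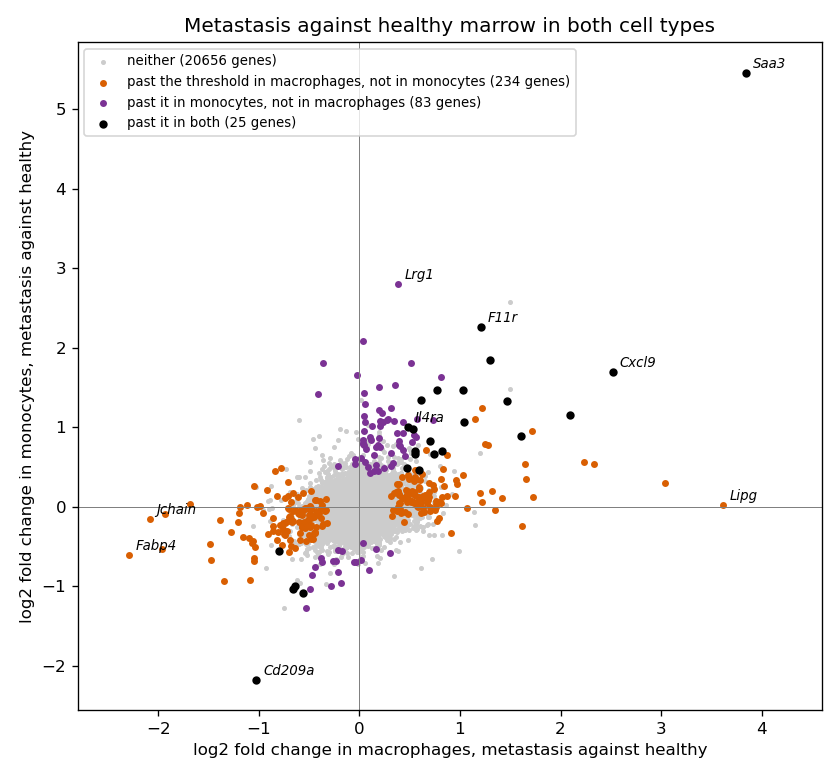
Log2 fold change of each of 20998 genes between metastasis and healthy marrow, in macrophages (horizontal) and monocytes (vertical), with colours for the genes past limma's threshold in one or both. The 25 genes past it in both, among them Saa3 (3.85 and 5.46) and Cd209a (-1.02 and -2.17), lie in the upper right and lower left; Lipg (3.62 and 0.02) and Lrg1 (0.38 and 2.81) lie close to the axes.

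The difference between the 2 metastasis effects was tested as an interaction. The metastasis effect on Lipg was higher in macrophages than in monocytes by 3.60 ± 0.42 (SE, adjusted p = 0.00026 in limma), and that on Dnase1l3, a secreted DNase gene, by 1.4 ± 0.20. Gm5483 (2.74 ± 0.50), Fam20c (0.94 ± 0.17), Lmtk2 (0.89 ± 0.17) and Nedd4 (0.70 ± 0.13) differed in the same direction. The effect on Lrg1 was lower in macrophages (-2.43 ± 0.25, adjusted p = 4.8e-05), as were those on Wfdc21 (-2.04 ± 0.38), Zfp36l1 (-1.83 ± 0.33), Il18rap (-1.68 ± 0.31), Gcnt2 (-1.18 ± 0.21) and Ms4a8a (-0.93 ± 0.17). That on the plasma cell gene Tnfrsf17 was lower too (-1.72 ± 0.25), since it fell in macrophages and stood at 0.03 ± 0.19 in monocytes. Wfdc21 stood at 11.9 ± 0.28 (SD) in healthy macrophages, near the highest value on any array, which left little room for a rise. These 13 genes, 6 positive and 7 negative, were all that passed of 20998; Gm5483 and Ms4a8a were named after their values were seen. Lipg, Dnase1l3, Lrg1 and Tnfrsf17 passed in each of the 19 fits with 1 array left out, and the other 9 genes lost their calls in 13 to 16 of them (adjusted p up to 0.122). The count was 48 without macrophages healthy replicate 5 and between 4 and 8 without macrophages healthy replicate 1, 2, 3 or 4, macrophages metastasis replicate 1, 3, 4 or 5, monocytes healthy replicate 1, 3, 4 or 5, or monocytes metastasis replicate 2 or 3. It was 6 with trend and robust moderation, 21 with array weights and 61 without both macrophage arrays that lay between the groups. Saa3 (-1.61 ± 0.59, adjusted p = 0.491) and Il4ra (-0.51 ± 0.15, adjusted p = 0.31) did not pass this test.

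Camera placed 8 lists past its threshold for the interaction. Cell cycle (median 0.30), T and NK cell (0.46), interferon-response (0.26) and neutrophil precursor genes (0.27) shifted upward in macrophages relative to monocytes, and lipid-associated (-0.31), B lineage (-0.29), marrow-resident macrophage (-0.22) and immediate early and stress genes (-0.20) shifted downward. None of these lists passed with an estimated correlation (adjusted p from 0.403 to 0.682) or with fry, and no member of any list passed in limma over all genes, among 1653 genes at an unadjusted p under 0.05. The call of the interferon list ended without monocytes metastasis replicate 3 (adjusted p = 0.365) and that of the neutrophil precursor list without macrophages healthy replicate 1 (0.147). That of the marrow-resident list ended in 9 of the 19 fits (up to 0.381, without macrophages healthy replicate 1) and with equal array medians (0.0806), and that of the immediate early list in 3 (up to 0.128, without macrophages metastasis replicate 2).

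The remaining comparisons asked how the sorted macrophages differ from the sorted monocytes in each kind of marrow. In healthy marrow, Gca was 64.3-fold (log2 6.01 ± 0.16, SE), Olfm4 39.6-fold (5.31 ± 0.26) and Orm1 37.6-fold (5.23 ± 0.26) higher in the macrophage arrays. The lactoferrin gene Ltf reached 12.3 ± 0.10 (SD, n = 5) against 7.40 ± 0.62 in monocytes (SD, n = 5). That is near the highest value on any array, where the scale can compress a difference, so no fold is given. Slco4c1 and Abca13 were 41.9-fold and 38.0-fold higher. Jchain, the immunoglobulin joining chain gene of plasma cells, stood at 10.3 ± 0.14 (SD) in macrophages. In monocytes it stood at 2.68 ± 0.31 (SD), within the 2.12 to 2.87 of Y-linked genes, so its fold has no exact value. Monocytes were higher in the granule protease gene Ctsg (-3.35 ± 0.17), in Rnase2a (-3.19 ± 0.23), Gria3 (-2.99 ± 0.22), the hepatocyte growth factor receptor gene Met (-2.97 ± 0.15), Papss2 (-2.69 ± 0.14) and Uck2 (-2.60 ± 0.21). By limma 5886 of 20998 genes passed, 2105 higher and 3781 lower in macrophages, with 968 differing by at least 2-fold (537 higher and 431 lower).

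MHC class II genes were higher in healthy macrophages. Of 10 MHC class II genes, 8 were higher and 1 lower, led by H2-Ab1 (2.48 ± 0.18, SE), Cd74 (1.61 ± 0.12) and H2-Aa (1.51 ± 0.14). The list kept its call with an estimated correlation (adjusted p = 0.0218). Of 11 MHC class I presentation genes 2 were higher and 2 lower, without a shift by camera (adjusted p = 0.433). Markers of other cells that carry MHC class II were higher in the same arrays, with a median of 0.88 for B lineage genes and 7 of 15 dendritic cell genes higher, Itgax (2.63 ± 0.22) among them. Camera placed the dendritic cell list higher (adjusted p = 0.000151, but adjusted p = 0.137 with an estimated correlation). The iron exporter gene Slc40a1 (4.09 ± 0.17), Vcam1 (2.05 ± 0.17) and Spic (1.37 ± 0.15) were among 9 higher of 20 marrow-resident macrophage genes. Camera placed this list higher (adjusted p = 0.00137, but adjusted p = 0.142 with an estimated correlation). Cd36 (4.40 ± 0.25), Cd9 (3.44 ± 0.17) and Cd63 (4.52 ± 0.14) were higher, while Lgals1 was lower (-1.96 ± 0.12). Tnf (2.21 ± 0.15), the chemokine gene Ccl5 (3.78 ± 0.27), Vegfa (2.32 ± 0.17), Mmp9 (3.02 ± 0.22) and the checkpoint ligand gene Cd274 (2.01 ± 0.18) were higher as well. These are single members: camera found no shift of the matrix remodelling (adjusted p = 0.433), glycolysis and hypoxia (0.445) and immune suppression lists (0.0670). It placed the pro-inflammatory list higher (0.00925), but not with an estimated correlation.

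Monocytes were higher in their own marker list and in growth and lysosomal genes. Of 16 Ly6C-high monocyte genes 13 were lower in macrophages, including F13a1 (-2.20 ± 0.17, SE), Fn1 (-1.67 ± 0.15) and Klf4 (-1.37 ± 0.13), and 1 was higher (estimated-correlation adjusted p = 0.032). Lysosomal genes were lower in 17 of 25, with Npc2 at -0.95 ± 0.11 and Lamp1 at -0.71 ± 0.07, against 2 higher (adjusted p = 0.0200 with an estimated correlation). Cell cycle genes were lower in 18 of 28, with Ube2c at -1.05 ± 0.13, and oxidative phosphorylation genes in 21 of 29, with Sdhb at -0.69 ± 0.07. These lists did not pass with an estimated correlation (adjusted p = 0.315 and 0.0780). The macrophage colony-stimulating factor receptor gene Csf1r (-0.51 ± 0.16), the F4/80 gene Adgre1 (-0.63 ± 0.15), Ccr2 (-0.83 ± 0.12), Msr1 (-1.86 ± 0.13) and Ly6c2 (-0.34 ± 0.11, near the top of the scale in both cell types) were lower in macrophages, and Itgam (0.92 ± 0.10) and Csf1 (0.42 ± 0.13) higher. Il4ra (0.15 ± 0.10), Flt1 (0.21 ± 0.18), Cx3cr1 (-0.17 ± 0.16) and Ccl2 (0.30 ± 0.22) did not pass. Csf1r lost its call after quantile normalization (adjusted p = 0.0748) and in 4 of the 10 fits with 1 array left out (up to 0.0770, without macrophages healthy replicate 5). Ly6c2 lost it in 3 (up to 0.0840, without macrophages healthy replicate 1) and Csf1 in 2 (up to 0.0545, without monocytes healthy replicate 4).

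Marker lists of other blood cells were higher in the healthy macrophage arrays. Maturing neutrophil genes had a median of 1.72, with 13 of 16 higher and 1 lower, among them Ltf, Ngp (3.03 ± 0.16, SE) and Padi4 (3.29 ± 0.16). B lineage genes had a median of 0.88, with 14 of 17 higher, including Cd79a (3.32 ± 0.37). T and NK cell genes had a median of 0.56, with 10 of 17 higher, including Cd3d (4.09 ± 0.19) and Gzma (3.53 ± 0.39). Erythroid genes were higher in 7 of 15 and megakaryocyte and platelet genes in 4 of 13. These 5 lists passed camera with an estimated correlation (adjusted p = 0.0200, 0.0200, 0.0490, 0.0446 and 0.0490), as did the osteoclast list (6 of 14 higher and 1 lower, adjusted p = 0.0490). Neutrophil precursor genes split, with Cebpe (3.34 ± 0.14) and Fcnb (3.24 ± 0.11) among 6 higher and Ctsg among 5 lower of 11. Of 22 epithelial tumour cell genes, some, among them Epcam, Spint2 and Ehf, were higher in these macrophages from mice without tumour (median 0.11, camera adjusted p = 0.0233, but adjusted p = 0.103 with an estimated correlation and 0.0827 after quantile normalization). The camera call ended without macrophages healthy replicate 1 (0.0523).

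In metastasis the same contrast gave 5563 genes past limma's threshold, 2015 higher and 3548 lower in macrophages, 969 of them by at least 2-fold (525 higher and 444 lower). The split was 2239 higher and 2907 lower after quantile normalization, and 1594 and 4188 with equal array medians. Jchain was again at that low level in monocytes (2.53 ± 0.15, SD), against 8.26 ± 0.92 (SD) in macrophages. Besides Jchain and Ltf, which lay near the ends of the scale, the named genes with the largest differences were Slco4c1 (5.71 ± 0.21, SE), Olfm4 (5.51 ± 0.27), Syne1 (5.19 ± 0.15) and Gca (5.13 ± 0.16). Rnase2a (-3.66 ± 0.24), Ctsg (-2.82 ± 0.18), Uck2 (-2.52 ± 0.23), Met (-2.44 ± 0.16), Papss2 (-2.39 ± 0.15) and Gria3 (-2.34 ± 0.24) were the lowest. Slc40a1 (4.50 ± 0.18), Cd63 (4.93 ± 0.15), H2-Ab1 (2.23 ± 0.19), Cd74 (1.77 ± 0.13), Vegfa (2.61 ± 0.18) and Cd36 (2.98 ± 0.26) were higher, as were the interferon-induced genes Cxcl10 (1.61 ± 0.24) and Ifit2 (1.49 ± 0.12). Klf4 (-1.85 ± 0.14), F13a1 (-1.96 ± 0.18), Msr1 (-1.67 ± 0.14), Adgre1 (-0.96 ± 0.16), Ccr2 (-0.82 ± 0.13) and Csf1r (-0.74 ± 0.17) were lower. Il4ra was lower in macrophages by -0.36 ± 0.11 (adjusted p = 0.017). The call was lost without macrophages metastasis replicate 3 or monocytes metastasis replicate 2, 3 or 4 (adjusted p = 0.0592, 0.0588, 0.0528 and 0.0524), in a fit of these 9 arrays alone (0.0520) and after quantile normalization (0.124). With an estimated correlation camera kept the MHC class II, maturing neutrophil, B lineage, T and NK cell, erythroid and megakaryocyte lists as higher and the lysosome and Ly6C-high monocyte lists as lower (adjusted p from 0.0147 to 0.0442). The medians were 1.98 for maturing neutrophil, 0.70 for B lineage and 1.17 for T and NK cell genes.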

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

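The test of array scaling on the neutrophil list and the plasma cell genes that were added were chosen after the results they concern were seen. The split of array positions by rising and falling genes was not among the tests set beforehand. The other tests were set before.

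Markers of neutrophils, B cells and T and NK cells were higher in the macrophage arrays than in the monocyte arrays. In healthy macrophages S100a9 stood at 12.2 ± 0.06 (SD, n = 5), Ltf at 12.3 ± 0.10, Jchain at 10.3 ± 0.14 and Cd3d at 8.24 ± 0.45 (SD), against 10.5 ± 0.22, 7.40 ± 0.62, 2.68 ± 0.31 and 4.15 ± 0.27 in healthy monocytes (SD, n = 5). A difference in scale between whole arrays is argued against by their medians, which lay between 4.45 and 4.55. After quantile normalization the maturing neutrophil list still lay 1.75 above the median of all genes. That test adds little, because the normalization had little to change. If other cells shared the macrophage sort in varying amounts, their genes would move together within the 10 macrophage arrays. After removal of group means the mean pairwise correlation was 0.389 for maturing neutrophil, 0.243 for B lineage and 0.252 for T and NK cell genes. These lay at percentiles 99.56, 100 and 100 of 10000 random lists matched on level, whose 95th percentiles were 0.255, 0.0589 and 0.0573. Genes regulated together within 1 cell type would also stand out against random genes, and no array was left out of this test. The percentiles therefore cannot tell other cells from expression by macrophages. Other blood cells, or their RNA, in the macrophage sort are a candidate explanation, which a gate on lineage markers would remove. Expression of such genes by marrow macrophages themselves stays open and was not tested. In healthy marrow Adgre1, and Csf1r with a call lost after quantile normalization, were lower in the macrophage arrays than in the monocyte arrays. How the mix of cells differed between healthy and metastasis marrow was not measured.

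B lineage genes were lower in macrophages from metastasis (median -0.24), with Jchain falling by 2.08 on the log2 scale, that is from 10.3 ± 0.14 to 8.26 ± 0.92 (SD, n = 5 each). A single array as the cause is argued against, since the list stayed lower in each of the 10 fits that left out 1 macrophage array, with a highest camera adjusted p of 0.00127, without metastasis replicate 1, although with an estimated correlation it did not pass (adjusted p = 0.341). A further list of 16 plasma cell genes, without the genes that had drawn attention, had a median of -0.50, with all 16 negative and 6 past the threshold in limma (camera adjusted p = 1.0e-14, and adjusted p = 0.0168 with an estimated correlation). Mzb1 (-1.39), Derl3 (-1.20) and Txndc5 (-0.98), chosen after their values were seen, were among them, and the list stood at a median of 0.05 in monocytes and differed between the cell types (interaction median -0.57, adjusted p = 0.0242 with an estimated correlation). In healthy monocytes Jchain lay within the range of Y-linked genes. For genes that low a fall cannot show in monocytes, and the interaction restates the fall in macrophages. Fewer plasma cells, or less of their RNA, in the macrophage sort from metastasis may account for the fall of Jchain and of the plasma cell list. This account does not cover Rag1 and Ebf1, the other B lineage genes that fell, and the cause of their fall was not tested. Whether plasma cells were fewer in the marrow itself was not measured.

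Macrophages healthy replicate 5 and metastasis replicate 2 lay between their groups. Over 100 genes chosen without these 2 arrays, on a scale of 0 at the healthy mean and 1 at the metastasis mean, both had a position of 0.52, while the other healthy arrays lay at or below 0.165 and the other metastasis arrays at or above 0.773. Scaling of the arrays is argued against, since the difference of their positions was -0.00881 after quantile normalization. The deposited medians of healthy replicate 5 and metastasis replicate 2, 4.50 and 4.55, already lay close, so this normalization had little to change. An exchange of 2 arrays that were otherwise like the rest of their groups is argued against by these positions. It would put healthy replicate 5 near 0.773 or above and metastasis replicate 2 near 0.165 or below. Whether 2 arrays that lay between the groups also had their labels exchanged cannot be told. The difference, -0.0027, fell between the bounds set for an exchange (above 0) and against it (below -0.5). The split that exchanges them gave 504 genes in place of 259 and goes with an exchange. At the 39 genes that rose healthy replicate 5 had a position of 0.21. Other healthy arrays had at most 0.266 there and other metastasis arrays at least 0.776. This position depended on the metastasis array left out with it, from 0.195 without replicate 1 to 0.508 without replicate 5. It therefore does not place healthy replicate 5 within the healthy range. At the 61 genes that fell healthy replicate 5 had 0.65, nearer to the other metastasis arrays (at least 0.721) than to the other healthy arrays (at most 0.223). Metastasis replicate 2 had 0.56 at the genes that rose and 0.49 at those that fell. A milder state of the marrow in one mouse, or a mixture of samples, could give such positions and was not tested.

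In limma, 13 genes differed in their metastasis effect between macrophages and monocytes, by a direct test of that difference. Lipg (3.60), Gm5483 (2.74), Dnase1l3 (1.4), Fam20c (0.94), Lmtk2 (0.89) and Nedd4 (0.70) had the higher effect in macrophages. Lrg1 (-2.43), Wfdc21 (-2.04), Zfp36l1 (-1.83), Tnfrsf17 (-1.72), Il18rap (-1.68), Gcnt2 (-1.18) and Ms4a8a (-0.93) had the lower effect there, Wfdc21 from a level near the top of the scale that left little room to rise, Tnfrsf17 because it fell in macrophages alone, and Gm5483 and Ms4a8a were named after their values were seen. By camera, 8 lists differed as well: cell cycle (median 0.30), T and NK cell (0.46), interferon response (0.26) and neutrophil precursor (0.27) upward. Lower were lipid-associated (-0.31), B lineage (-0.29), marrow-resident macrophage (-0.22) and immediate early genes (-0.20), and none of the 8 passed with an estimated correlation (adjusted p from 0.403 to 0.682). In monocytes the B lineage and T and NK cell lists lay little above the epithelial tumour cell list. For the B lineage list this left little room for a fall there. It would not have limited a rise of the T and NK cell list, so it does not bear on that interaction.

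Single arrays far from the rest of their group were found in 49 of 640 groups of values tested (131 genes and 29 lists), where chance gives about 1 in 20, or 32. Macrophages healthy replicate 1 held 11 of them: it was highest for Cfb (6.14), Ccl2 (6.29) and H2-Ab1 (10.54), and lowest for Itgb3 (6.32), S100a9 (12.05), Wfdc21 (11.44), Il1f9 (5.16), Fcnb (10.64), Cebpe (9.81), Slc40a1 (7.37) and Cd9 (8.15). Macrophages metastasis replicate 2 held 9: lowest for Cxcl9 (8.52), Cxcl11 (5.97), Oas2 (5.76), Tgfbi (9.28), Wfdc21 (11.59), Ly6c2 (11.88) and Gm5483 (4.34), and highest for Jchain (9.88) and Dennd5b (3.68). Macrophages healthy replicate 5 was lowest for Slc12a2 (6.46), Fabp4 (5.85) and Pparg (5.25). Among the other macrophage arrays, Iigp1 was highest in healthy replicate 4 (4.17), Ngp (12.15), S100a9 (12.18) and Ms4a8a (4.92) in metastasis replicate 1, Oasl2 (6.58) in metastasis replicate 3 and Car1 (4.12) in metastasis replicate 5. Vegfa (7.17) and Nedd4 (8.07) were lowest in metastasis replicate 4. Among healthy monocytes, Kif11 (8.72) was lowest in replicate 1, Cebpe (6.62) and Vcam1 (3.85) were lowest and Ier3 (5.85) highest in replicate 2. Xcl1 (4.53) was lowest and the mean of MHC class I presentation genes (8.10) highest in replicate 3, Ms4a8a (5.27) was highest in replicate 4, and H2-Ab1 (7.10) lowest in replicate 5. Among metastasis monocytes, Cfb (6.45), Il4ra (8.17) and Padi4 (3.95) were lowest in replicate 1, Hpgd (5.21) and Uck2 (8.56) highest and Cd9 (5.40) lowest in replicate 2. In this group Mmp19 (7.34) was highest and Gria3 (7.13) lowest in replicate 3, and Cxcl10 (5.93) and Gzma (4.28) highest in replicate 4.

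Regroupings of the same arrays gave a result as large in at most 2 of 100 splits in each comparison, the real one included. They treat the arrays as exchangeable, although the labels did not say that these came from separate mice. In macrophages 2 of the 100 splits, the real one with 259 genes included, gave at least as many genes. The highest other gave 504, from the split that exchanges healthy replicate 5 and metastasis replicate 2, which points to a structure of these arrays. For monocytes (108 genes against at most 23 in another split), for cell types in healthy marrow (5886 against 1659) and in metastasis (5563 against 3767), and for the correlation of the effects (0.264 against 0.204), 1 split of 100, the real one, gave as much. For the interaction (13 genes) 2 of 100 did, and the highest other gave 21. These regroupings redrew the metastasis labels within each cell type. They ask whether metastasis has any effect, and cannot decide whether the effects differ between the cell types.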

How the results depend on the processing

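Of the alternatives, the fits without 1 array of each group that correlated least with its own group, and without macrophages healthy replicate 5 and metastasis replicate 2, were chosen after seeing the data; the others were planned. No named gene or list past its threshold turned its direction in the fits run for it. For genes these were the fits with 1 array left out, with array weights, of the compared groups alone and after quantile normalization. Of 145 list medians (29 lists in 5 comparisons), 22 changed sign after quantile normalization or with equal array medians, none of a list past camera's threshold under any of these scalings. The balance of higher and lower genes did turn. In macrophages it went from 134 higher and 125 lower to 144 and 154 after quantile normalization, 96 and 145 with equal array medians and 353 and 373 without healthy replicate 5 and metastasis replicate 2. Without healthy replicate 2, 3 or 5 alone it was 98 and 99, 93 and 98, and 267 and 279. In the interaction, with 6 higher and 7 lower, it went to 5 and 2 without macrophages healthy replicate 4, to 3 and 2 without metastasis replicate 3, and was even in 9 further fits. Between cell types more genes were lower in macrophages, except with the 2-fold threshold (537 higher and 431 lower in healthy marrow, 525 and 444 in metastasis). In metastasis the split of 2015 higher and 3548 lower was 2239 and 2907 after quantile normalization and 1594 and 4188 with equal array medians. Alternatives on several probe sets per gene could not be run, since the table holds 1 value per gene. Where a count moved and nothing else is said, the cause was not tested.

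In macrophages, the 259 genes that differed between metastasis and healthy marrow became 134 with array weights (132 shared), 65 in a fit of these arrays alone (64 shared), 54 with an added 2-fold threshold, which by construction only removes genes, and 726 without healthy replicate 5 and metastasis replicate 2 (237 shared). They were 338 with trend and robust moderation, 344 with dim genes left out, 298 after quantile normalization, 241 with equal array medians, 219 without the 4 arrays that stood apart, and from 153 to 546 with 1 array left out. In monocytes, the 108 genes became 328 with array weights, 210 in a fit of these arrays alone (93 shared) and 42 with the 2-fold threshold, and from 61 to 131 with 1 array left out. The 5886 and 5563 genes that differed between cell types in healthy marrow and metastasis became 968 and 969 with the 2-fold threshold, and from 5290 to 5884 and from 4909 to 5448 with 1 array left out; under the other settings they ranged from 5450 to 5938 and from 5086 to 6192. The 13 interaction genes became 6 with trend and robust moderation, 21 with array weights, 61 without the 2 macrophage arrays between the groups (20 higher, 41 lower), and from 4 to 48 with 1 array left out, and with equal array medians they were 14 (4 higher, 10 lower). The correlation of the metastasis effects, 0.264, became 0.523 over genes past the threshold in at least 1 cell type and 0.340 with dim genes left out, and ranged from 0.237 to 0.286 with 1 array left out.

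Camera placed 12 lists past its threshold in macrophages, 4 in monocytes, 19 and 17 between cell types in healthy marrow and metastasis, and 8 for the interaction. With an estimated correlation these became 0, 0, 9, 8 and 0, since that test takes the correlation of a list's genes from the arrays. With fry they became 4 in macrophages, 0 in monocytes and 0 for the interaction, and 22 and 21 between cell types. The 4 lists of monocytes also became 0 with dim genes left out and 0 after quantile normalization. With 1 array left out they ranged from 9 to 12, from 2 to 6, from 17 to 19, from 15 to 19 and from 5 to 10.

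Of the named genes past the threshold, 24 of 49 in macrophages, 17 of 32 in monocytes, 50 of 53 and 30 of 31 between cell types, and 4 of 13 in the interaction passed in each of the fits run for genes. Among calls on named genes, a fit of the compared groups alone ended 30, array weights 18 and quantile normalization 9. Leaving 1 array out ended a call in 320 pairs of gene and fit and made 4 new ones. The largest shift of a comparison's median over all genes was 0.02 by quantile normalization and 0.06 by equal medians. Signal over background limits the dim genes: the median gene mean was 4.51, and the Y-linked genes, which female mice lack, had a median of 2.49.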

Other observations

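The test of T and NK cell genes below was chosen after the result was seen, and both added lists were chosen after the values were seen.

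Plasma cell genes separated the sorts in healthy marrow: of the 16 added plasma cell genes, 10 were higher in macrophages than in monocytes and 1 was lower (median 0.70, camera adjusted p = 3.8e-07, and adjusted p = 0.0472 with an estimated correlation). In metastasis 4 were higher and 1 lower, with a median of 0.04 (camera adjusted p = 0.154). Further members that fell in macrophages from metastasis were Eaf2 (-0.92), Trp53inp1 (-0.86) and Prdm1 (-0.56), the last a regulator of plasma cell formation; they were chosen after their values were seen.

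The joint rise of Saa3 and of the chemokine genes Cxcl9, Cxcl10 and Cxcl11 in macrophages from metastasis raised the hypothesis of a response to interferon gamma, which T and NK cells are known to secrete. Of 15 further interferon-gamma-inducible genes, 13 had positive fold changes in macrophages, with a median of 0.39 and a mean of 0.37 (95% interval 0.15 to 0.58), and the list was higher by camera (adjusted p = 3.1e-06, but adjusted p = 0.131 with an estimated correlation). The only member past the threshold over all genes was Gbp4 (0.75 ± 0.19, SE, adjusted p = 0.049 in limma), chosen after its value was seen. The T and NK cell list, with a median of 0.43 and a mean of 0.30 (95% interval 0.02 to 0.59), was also higher in these arrays by camera. That call was lost with an estimated correlation (adjusted p = 0.341) and with dim genes left out (0.0765), and Cd3d stood at -0.39. Cells of that kind in the macrophage sort may go with the response or carry part of it, which these values leave open. In monocytes the added interferon gamma list had a median of -0.00131, which meets the bound set beforehand against such a response, but its members went both ways. Their mean was 0.10 (95% interval -0.13 to 0.33), so that neither a small rise nor none is excluded and monocytes stay undecided. Camera found no shift of the list there (adjusted p = 0.361). Saa3 and Cxcl9 nonetheless rose in monocytes (log2 5.46 and 1.69), so the list gives no ground for tying those rises to interferon gamma. The difference between the cell types was 0.24 in the median (camera adjusted p = 0.0108, but adjusted p = 0.405 with an estimated correlation).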
